A study of Mus musculus with 16 samples.

How the data were processed

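RNA from the gastrocnemius muscle of 16 male mice on a C57Bl6J background was measured on Affymetrix Mouse Gene 1.0 arrays, 1 array per mouse. Per the labels' protocols the mice had eaten a diet with 40% of calories from butter fat for at least 8 weeks. Arrays were grouped by genotype and line as their labels give them, with 4 arrays in each of 4 groups. The labels name separate animals, so replicates are mice, and the number of arrays limits the precision of every value.

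The deposited log2 values were made by the authors with GCOS 1.0 and RMA (robust multi-array average: background correction, quantile normalization and summary per probe set), per the submitters' processing notes. Whether both lines were normalized together, any filter and the genome build are not given in the sources used here. A second deposited log2 table held the same 35557 probe sets, and 0 of its values differed from the first. The deposited ratio columns, per the file headers a normalized form of the same arrays, equalled the linear value divided by the median of the line and were used for that check. All 48 columns of per-sample values were matched to a sample by name.

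Gene names came from the platform's annotation table, which listed 23410 probe sets. Exactly 1 gene symbol was given for 21789 of them and several for 1621, and 12147 probe sets were not listed and are unnamed here. Gene IDs of 21698 single-symbol probe sets were found in a RefSeq gene table, and 0 symbols needed an update. That table served for names and for which genes neighbour each other, and no coordinates are printed because the array's build is not given. For 129 single-symbol probe sets all 16 values equalled those of another probe set. No gene was named from a probe set with several symbols.

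The tested set held the 15252 transcript clusters (probe sets with 1 symbol, 13919 genes) whose mean over all arrays was at or above the 30th percentile, a log2 value of 6.18, and 6537 clusters fell below it. Group means were fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, which left 12 residual degrees of freedom. Variances were moderated with an intensity trend (median prior degrees of freedom 5.71). Each cluster has a common variance over all groups, so an SE or p in either line also rests on the spread in the other. P-values were adjusted by the Benjamini-Hochberg method over all tested clusters, and an adjusted p under 0.05 was called. The contrasts were KO minus WT in each line, their mean, their difference, and WT against WT. Single genes were also compared by a two-sided exact permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286.

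Gene lists were fixed before the data were examined, 32 in all with 701 entries, of which 651 matched a single-symbol probe set. Each gene was represented by its cluster with the highest mean. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and alternatively with a correlation estimated per list and with fry. Fry tests whether a list's genes move one way on balance, without comparing them with other genes. Members were also adjusted over the list alone. That adjustment does not correct for the number of lists or comparisons, so such calls are weaker than calls over all clusters. The list tests between WT groups were added after the data were seen.

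The genes named were set by a rule fixed before the data were examined. It takes the targeted genes, Myl1, the other calcineurin subunits, Rcan1 and 4 adult myosin heavy chains. For each line and the mean effect it takes the 10 called clusters with the smallest p per direction, or where fewer than 5 are called the 5 with the smallest p, given as values. For the difference it takes the 5 with the smallest p, and for each list called, or holding a member called over the list alone, up to 4 members with the smallest p. Predicted genes are passed over. Where fewer than the allowed members of a list are named, the choice among them was made for length.

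Alternatives covered the filter, a repeated quantile normalization, fitting each line alone, array weights, the variance prior, 1 cluster per gene, the threshold, the series of animal numbers as a block in the Ppp3r1 line, and each array left out in turn. The functions were tested on simulated data made from the real means and spreads, after a first fit to the arrays had been looked at. Noise was drawn independently for each cluster, with the same spread in all groups. Real groups differ in spread and real genes move together, so the recovery below may be overstated. With changes added to part of the 15252 clusters in the Ppp3r1 comparison, 71.6% of those changed by 0.5 on the log2 scale were recovered, 98.7% of those changed by 1 and 100% of those changed by 2, with 9 false calls. In the Ppp3cb comparison the shares were 67.2%, 97.4% and 100%, with 16 false calls. A list of independent genes shifted by -0.3 in the Ppp3r1 comparison was called over 13919 genes, with 0 other lists.

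Ppp3cb values disagreed with the label of 4 arrays, as reported first. The labels were kept in every comparison, and counts without these arrays were added after seeing the data. A refit with arrays grouped by their Ppp3cb value was run once and is left out, because groups defined by a measured value are not the study's groups. That grouping is also 1 of the 35 possible splits of the line's arrays, the one with the most calls, and its count is given as such. All mice are labelled male: Xist lay between 4.62 and 5.20 on the 16 arrays, under the filter value, while Eif2s3y lay between 8.45 and 9.77. Clusters without a single symbol were left out of the main tests. At the same filter value 7298 of them gave 0 calls in both KO comparisons. Figures were drawn with matplotlib 3.10.9.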

Results

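Gene expression was measured in gastrocnemius muscle of fat-fed male mice that lack a subunit of calcineurin, the calcium-dependent phosphatase that acts on NFAT transcription factors. The first line is a whole-body knockout (KO) of Ppp3cb, the beta catalytic subunit. The second lacks Ppp3r1, the regulatory subunit, in skeletal muscle through a Cre recombinase expressed from the Mlc1f (Myl1) gene. Each line has 4 KO arrays and 4 arrays of wild-type (WT) littermates. Array medians over all probe sets parted by line. They lay between 6.68 and 6.77 on the log2 scale in the Ppp3cb line and between 6.81 and 6.94 in the Ppp3r1 line. Arrays of a group correlated between 0.962 and 0.991.

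The targeted genes were read first, since they check the labels. Ppp3cb (probe set 10417895) did not separate the groups of its own line. On the arrays labelled Ppp3cb KO its log2 value was 10.48 in animal 18, 10.22 in animal 5, 11.74 in animal 6 and 11.61 in animal 9. On those labelled Ppp3cb WT it was 11.80 in animal 12, 11.67 in animal 2, 10.37 in animal 23 and 10.23 in animal 24. On the 8 arrays of the Ppp3r1 line, where the gene is intact, it lay between 11.47 and 11.70. So 2 of 4 arrays labelled KO were at the intact level, 2 of 4 labelled WT were more than 0.5 below it, and 4 arrays went against their label. The mean was 11.01 ± 0.78 (SD, n = 4) in arrays labelled KO and 11.02 ± 0.83 (SD, n = 4) in arrays labelled WT (two-sided exact permutation p = 0.971). The labels are kept below, and no direction in this line can be assigned to loss of Ppp3cb.

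Ppp3r1 (probe set 10374415) followed its labels. It was 9.17 ± 0.14 (SD, n = 4) in Ppp3r1 KO and 9.49 ± 0.14 (SD, n = 4) in WT muscle, with every KO array below every WT array (two-sided exact permutation p = 0.0286, the smallest possible). The log2 change was -0.32 (SE 0.13), with a limma adjusted p of 0.372. The probe set may include exons that were not deleted, and whole muscle holds other cells. The other subunits Ppp3ca, Ppp3cc and Ppp3cb differed by -0.06 (SE 0.10), 0.04 (SE 0.13) and -0.07 (SE 0.34) in this line, none of them called. The SE of Ppp3cb reflects its wide spread in the other line, since its SD here was 0.05 in KO and 0.11 in WT. With each array left out in turn the differences of Ppp3ca, Ppp3cc and Ppp3cb ranged from -0.09 to -0.01, from -0.05 to 0.13 and from -0.12 to -0.04. Rcan1, a calcineurin inhibitor that NFAT induces, had a log2 difference of -0.12 (SE 0.30), with a range of -0.23 to 0.08 over the same omissions. Myl1, which carries the Cre, was 13.85 ± 0.06 (SD, n = 4) in KO and 14.02 ± 0.04 (SD, n = 4) in WT (two-sided exact permutation p = 0.0286).

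**Figure D1:**
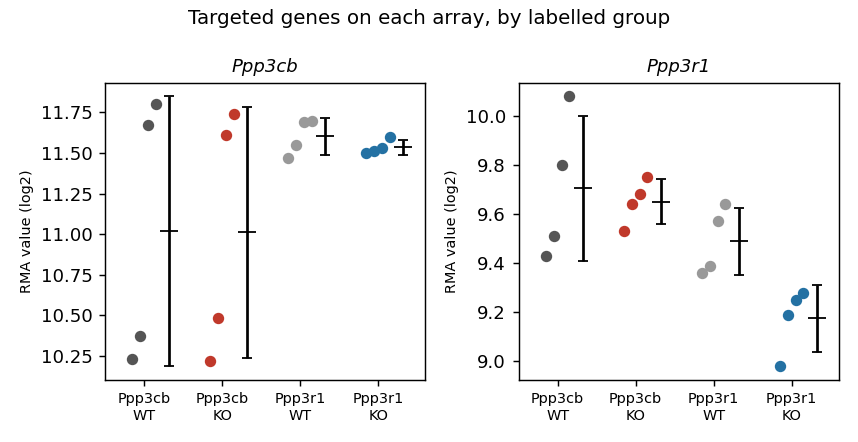
RMA log2 value (vertical axes) of Ppp3cb and Ppp3r1 on each of 16 arrays, by labelled group; points are mice and bars the mean ± SD of 4. Both groups labelled Ppp3cb hold 2 arrays near 11.7 and 2 near 10.3, while Ppp3r1 is lower in every KO than in every WT array of its own line.

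Muscle labelled Ppp3r1 KO was compared with that of WT littermates to ask which transcripts depend on calcineurin in this tissue. The array titles do not say whether the WT littermates carry the Cre allele. If they do not, its effects cannot be told apart from loss of Ppp3r1 in any comparison of this line. Myh2 (probe set 10377055), the myosin heavy chain of fast oxidative type IIa fibres, fell by 2.08 on the log2 scale (SE 0.25, a 4.24-fold difference, limma adjusted p = 0.00186). Its mean was 9.97 ± 0.52 (SD, n = 4) in KO against 12.05 ± 0.51 (SD, n = 4) in WT, and all 4 KO arrays lay below all 4 WT arrays. Myh1, the type IIx chain, was 13.11 ± 0.17 (SD, n = 4) against 12.63 ± 0.12 (SD, n = 4), a log2 difference of 0.48 (SE 0.13) that was called over the fast fibre list alone (limma adjusted p = 0.0192) and not over all clusters (0.363). Myh4, the type IIb chain, differed by -0.06 (SE 0.05), and Myh7, the slow type I chain, by 0.51 (SE 0.56), or by -0.09 without WT animal 415. Myh4 lay between 13.99 and 14.15 on the arrays of this line, near their maxima of 14.94 to 15.04. Whether values this high understate differences was not tested.

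**Figure D2:**
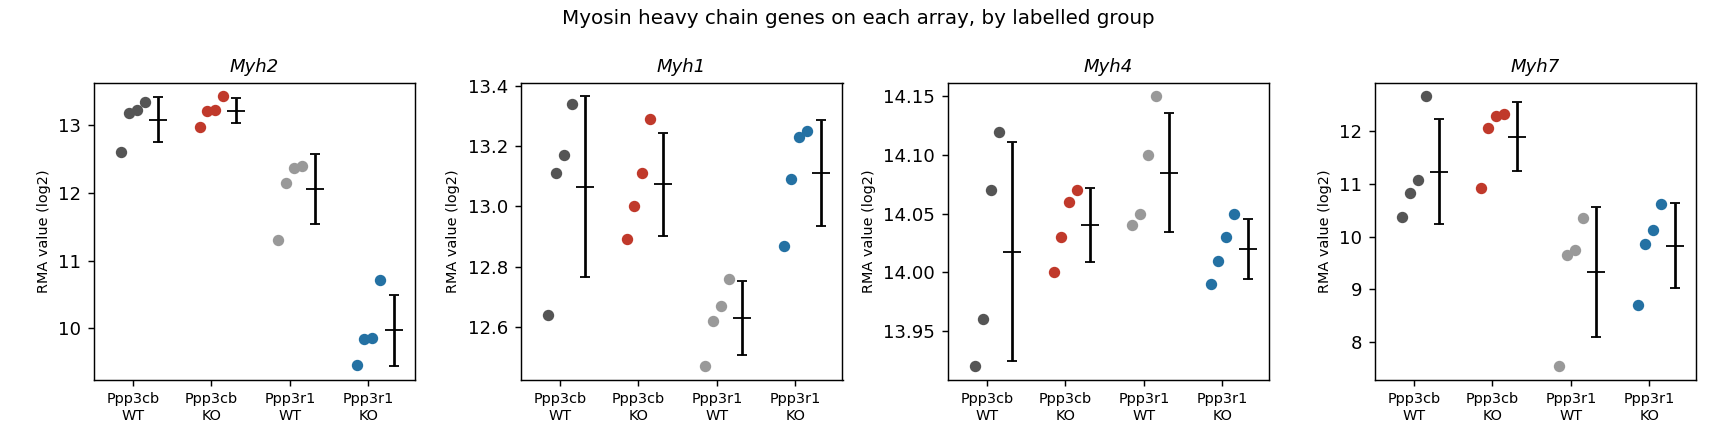
RMA log2 value (vertical axes, each with its own range) of 4 adult myosin heavy chain genes on each array, by labelled group; points are mice and bars the mean ± SD of 4. Myh2 lies between 9.46 and 10.71 in Ppp3r1 KO and between 11.30 and 12.40 in its WT.

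Myh2 was the 1 cluster called of 15252, against 1787 at an unadjusted p under 0.05, where 762.6 would be expected by chance. Most other splits of the arrays of the Ppp3r1 line gave fewer than 1787, but some gave more, up to 3609. Splits with KO and WT arrays mixed equally gave up to 3521. The excess over 762.6 therefore does not set the labels apart from other groupings. Myh2 lost its call when the Ppp3r1 line was fitted alone, without the spread of the other line (limma adjusted p = 0.0691, same log2 change). Counts were 12 without KO animal 416, 3 without the Ppp3cb-line animal 12 and 2 without KO animal 331. Uncalled clusters with the smallest p included Lancl1, with a log2 difference of -0.64 (SE 0.11, limma adjusted p = 0.087), and Kcnq5, a potassium channel, with -0.78 (SE 0.14). Adamts3 and Cmss1 had -0.39 (SE 0.08) and -0.73 (SE 0.16). On the other side Atp1b4 had 1.33 (SE 0.23, limma adjusted p = 0.111) and Gbe1, the glycogen branching enzyme, had 0.59 (SE 0.11). Zbtb48, Omp and Bhlha9 had 0.37 (SE 0.08), 0.39 (SE 0.09) and 0.36 (SE 0.08). Without KO animal 416 the limma adjusted p was 0.0366 for Lancl1, 0.0331 for Kcnq5 and 0.0322 for Cmss1. Without the Ppp3cb-line animal 12 it was 0.0124 for Atp1b4 and 0.0309 for Gbe1. For Atp1b4 it was 0.0476 without KO animal 331 and 0.0244 with array weights. Other omissions gave up to 0.29 for Lancl1, 0.608 for Kcnq5, 0.843 for Cmss1, 0.317 for Atp1b4 and 0.613 for Gbe1.

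Among the gene lists, those of mitochondrial metabolism were lower in Ppp3r1 KO muscle with the preset correlation. Of 76 subunits of oxidative phosphorylation 71 were lower, with a median log2 change of -0.16 (camera adjusted p = 2.19e-12; adjusted p = 0.588 with an estimated correlation), and 0 were called over the list alone. Cycs, the electron carrier cytochrome c, had -0.27 (SE 0.07) and Ndufs5 of complex I had -0.51 (SE 0.14). Of 20 genes of the tricarboxylic acid cycle 18 were lower (median -0.22, camera adjusted p = 2.85e-06; adjusted p = 0.588 with an estimated correlation). Dld and Suclg1 fell over the list alone, by 0.43 (SE 0.12) and 0.32 (SE 0.10), calls that were lost on leaving out any of 6 of the 16 arrays (highest limma adjusted p = 0.178, without WT animal 334). Of 31 genes of fatty acid uptake and oxidation 24 were lower (median -0.20, camera adjusted p = 7.67e-05; adjusted p = 0.588 with an estimated correlation), and Decr1, an enzyme of unsaturated fat oxidation, fell over the list alone by 0.55 (SE 0.14), a call lost on leaving out any of 3 arrays (highest limma adjusted p = 0.131, without WT animal 334). Calcium handling was lower in 23 of 28 genes (median -0.15), with Hrc at -0.30 (SE 0.10) and the mitochondrial uniporter Mcu at -0.28 (SE 0.10). Mitochondrial fission and fusion was lower in 19 of 21 (median -0.13), with Dnm1l at -0.30 (SE 0.11). The camera adjusted p was 4.50e-05 for calcium handling and 0.000813 for fission and fusion, and both had adjusted p = 0.588 with an estimated correlation.

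Fast fibre proteins were lower in 12 of 16 genes (median -0.08, camera adjusted p = 0.00657; adjusted p = 0.588 with an estimated correlation). Over this list alone Tnnc2, the fast troponin C, fell by 0.23 (SE 0.07), while Myh1 rose as given above. Myl1, which carries the Cre in this line, fell by 0.17 (SE 0.05), and an effect of the Cre allele on it was not tested. The calls of Tnnc2 and Myl1 were lost without KO animal 414 (limma adjusted p = 0.0711) and without WT animal 334 (0.0805), and that of Myh1 held with each array left out (highest 0.0451). Slow fibre proteins were higher in 13 of 16 genes (median 0.21) and were not called (camera adjusted p = 0.44). The list of calcineurin regulators with NFAT and MEF2 factors was lower in 12 of 19 (median -0.06, camera adjusted p = 0.0402; adjusted p = 0.588 with an estimated correlation). In it Akap6 had -0.54 (SE 0.19) and Mef2c -0.33 (SE 0.13). Without KO animal 331 Akap6 had -0.36, and without KO animal 414 Mef2c had -0.20.

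The muscle atrophy programme was higher in 18 of 20 genes (median 0.33, camera adjusted p = 7.43e-05; adjusted p = 0.588 with an estimated correlation). Over this list alone 4 genes rose. Eif4ebp1, a repressor of translation, rose by 0.92 (SE 0.26), the transcription factors Klf15 and Foxo3 by 0.48 (SE 0.15) and 0.34 (SE 0.11), and the metallothionein Mt2 by 1.58 (SE 0.54). Each of these calls was lost on leaving out any of at least 7 of the 16 arrays (highest limma adjusted p = 0.208, without KO animal 414). Without that animal Eif4ebp1 had 0.57. Immediate early genes were higher in 20 of 22 (median 0.16, camera adjusted p = 0.00657; adjusted p = 0.588 with an estimated correlation), and the nuclear receptor Nr4a3 rose over the list alone by 1.07 (SE 0.27), a call lost on leaving out any of 4 arrays (highest limma adjusted p = 0.0704, without WT animal 336). Genes of the integrated stress and unfolded protein response were higher in 16 of 21 (median 0.13, camera adjusted p = 0.0269; adjusted p = 0.588 with an estimated correlation), with Xbp1 at 0.40 (SE 0.14). Insulin signalling genes were higher in 18 of 23 (median 0.13, camera adjusted p = 0.0364; adjusted p = 0.588 with an estimated correlation), with Akt1 at 0.67 (SE 0.21) and Pik3r1 at 0.75 (SE 0.25), or 0.40 and 0.50 without KO animal 414.

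Lists of markers of other cell types were called as well. Tendon markers were lower in 7 of 11 genes (median -0.23, camera adjusted p = 0.0402; adjusted p = 0.606 with an estimated correlation). Fmod, Thbs4 and Kera, matrix proteins of tendon, fell over that list alone by 1.20 (SE 0.32), 0.82 (SE 0.25) and 0.56 (SE 0.19). These calls were lost on leaving out any of at least 4 arrays (highest limma adjusted p = 0.111, for Kera without WT animal 415). Fibroblast and matrix markers were lower in 16 of 20 (median -0.17, camera adjusted p = 0.00657; adjusted p = 0.696 with an estimated correlation), with Lum at -0.45 (SE 0.20), or -0.27 without KO animal 414. Schwann cell markers were higher in 11 of 11 (median 0.10, camera adjusted p = 0.0416; adjusted p = 0.588 with an estimated correlation), with Mbp at 0.23 (SE 0.11). In all, 14 of 32 lists were called, 5 higher and 9 lower, and 0 with an estimated correlation or with fry. The count was 9 without KO animal 331 and 9 without WT animal 336. Other splits of the same 8 arrays called up to 16 lists, the highest in a split 1 exchange of arrays away from the labels.

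**Figure D3:**
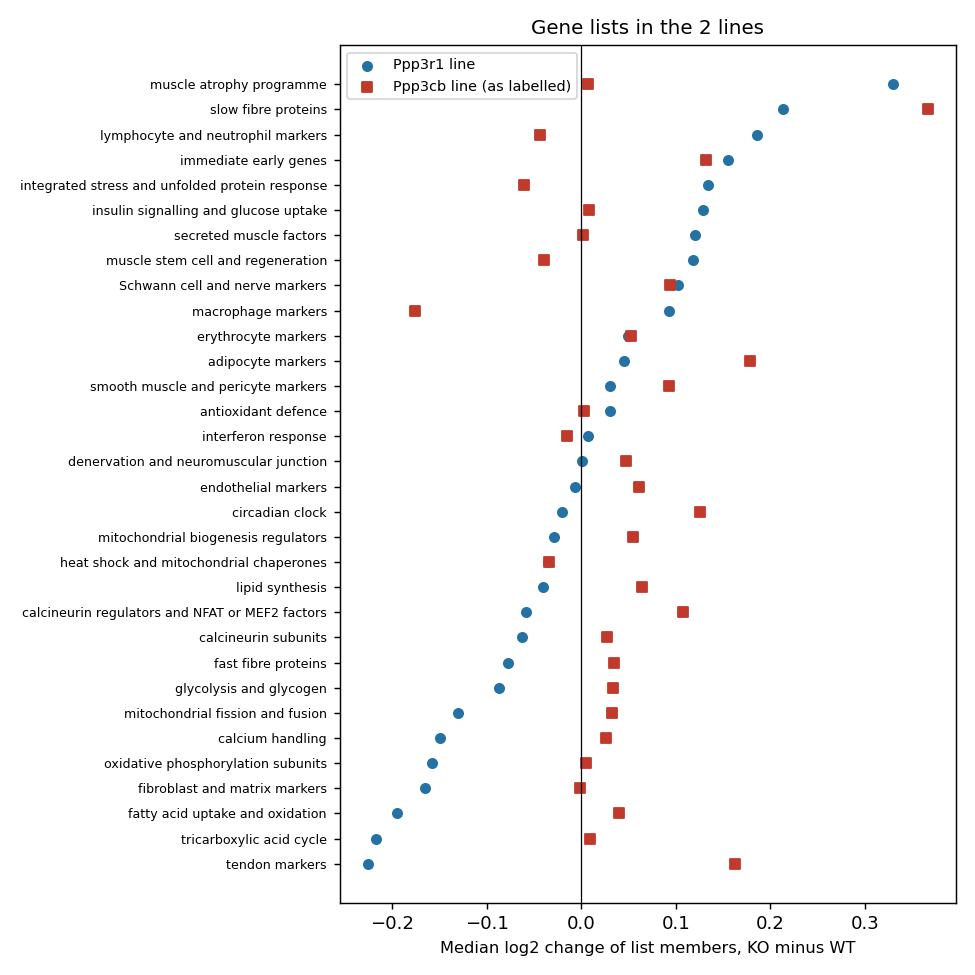
Median log2 change of the measured members of each of 32 gene lists (horizontal axis, KO minus WT) in the Ppp3r1 line (circles) and in the Ppp3cb line as labelled (squares). Oxidative phosphorylation lies at -0.158 in the Ppp3r1 line and at 0.00526 in the Ppp3cb line as labelled.

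The arrays labelled Ppp3cb KO were compared with those labelled WT in the same way, and the directions below are those of the labels, which Ppp3cb itself contradicts on 4 arrays. No cluster of 15252 was called with limma, and 264 had an unadjusted p under 0.05, fewer than the 762.6 expected by chance. The smallest p lower in arrays labelled KO belonged to the chemokines Ccl9 and Ccl6, with log2 differences of -0.62 (SE 0.13) and -0.65 (SE 0.15), then Wfdc17 with -0.89 (SE 0.24), Serpinb1a with -0.60 (SE 0.17) and Krt33a with -0.43 (SE 0.13). On the higher side Cmtm4 had 0.30 (SE 0.08), Chad, a cartilage matrix protein, 0.86 (SE 0.24), H4c8 0.30 (SE 0.08), Krt14 1.05 (SE 0.29) and Myh9 0.35 (SE 0.10). Without the array labelled KO of animal 9, 2 clusters were called, among them Krt14 (limma adjusted p = 0.00893). Without the 4 arrays at odds with their label, chosen after seeing the data by the targeted gene itself, 14 clusters were called.

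Of 32 lists 10 were called in this line, 8 higher and 2 lower in arrays labelled KO, and 0 with an estimated correlation (smallest adjusted p = 0.79 with an estimated correlation) or with fry. No member of these lists was called over its list alone. Macrophage markers were lower in 13 of 16 genes (median -0.18, camera adjusted p = 0.000125; adjusted p = 0.79 with an estimated correlation), with Cd163 at -0.31 (SE 0.15) and C1qc at -0.36 (SE 0.19). Without animal 18 these were -0.19 and -0.16, and without animal 12 Cd163 was -0.18. Tendon markers were higher in 9 of 11 (median 0.16, camera adjusted p = 0.00137; adjusted p = 0.79 with an estimated correlation), with Tnmd at 0.56 (SE 0.18). Slow fibre proteins were higher in 15 of 16 (median 0.37, camera adjusted p = 0.00186; adjusted p = 0.79 with an estimated correlation), with Myl3 at 0.98 (SE 0.53) and Casq2 at 0.32 (SE 0.19). Myl3 was 0.55 without animal 24 and Casq2 0.10 without animal 12. Immediate early genes were higher in 18 of 22 (median 0.13, camera adjusted p = 0.00214; adjusted p = 0.79 with an estimated correlation), with Btg2 at 0.45 (SE 0.15) and Ier5 at 0.22 (SE 0.09). Genes of the integrated stress response were lower in 13 of 21 (median -0.06, camera adjusted p = 0.00222; adjusted p = 0.79 with an estimated correlation), with Asns at -0.89 (SE 0.36) and Mthfd2 at -1.09 (SE 0.44), or -0.35 and -0.37 without the array labelled WT of animal 24. The count of lists was 3 without animal 9 and 4 without the 4 arrays at odds with their label.

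The remaining 5 called lists in this line were all higher in arrays labelled KO. Schwann cell markers were higher in 11 of 11 genes (camera adjusted p = 0.00214), circadian clock genes in 13 of 17 (0.0466), fast fibre proteins in 15 of 16 (0.0466), adipocyte markers in 11 of 14 (0.0466) and calcineurin regulators in 16 of 19 (0.0475). With an estimated correlation the adjusted p = 0.874 for adipocyte markers and 0.79 for the other 4.

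The mean of the KO effects averages both lines, so a change in 1 line alone can carry it, and it rests on the contradicted labels of the Ppp3cb line. No cluster was called with limma (943 at an unadjusted p under 0.05). Myh2 had the smallest p, with a mean log2 difference of -0.98 (SE 0.17, limma adjusted p = 0.393). Lancl1 had -0.40 (SE 0.08), Sf3b4 -0.36 (SE 0.08), Ndufs5 -0.45 (SE 0.10) and Ptgs2 -0.34 (SE 0.08). Tfap4 had 0.26 (SE 0.06), Atp1b4 0.74 (SE 0.17), Nr4a3 0.81 (SE 0.19), Llgl2 0.31 (SE 0.08) and Fam43b 0.35 (SE 0.09). Immediate early genes were higher in 21 of 22 (median 0.14, camera adjusted p = 0.00012; adjusted p = 0.985 with an estimated correlation), and Nr4a3 and Btg2 rose over that list alone, Btg2 by 0.36 (SE 0.10). The call of Btg2 was lost on leaving out any of 8 of the 16 arrays (highest limma adjusted p = 0.0821, without the array labelled Ppp3cb KO of animal 5). Oxidative phosphorylation was lower in 63 of 76 (median -0.08, camera adjusted p = 1.78e-09; adjusted p = 0.985 with an estimated correlation), and Ndufs5 fell over that list alone, a call lost on leaving out any of 9 arrays (highest limma adjusted p = 0.083). Schwann cell markers were higher in 11 of 11 (camera adjusted p = 0.000891; adjusted p = 0.985 with an estimated correlation). Slow fibre proteins were higher in 14 of 16 (camera adjusted p = 0.0184) and the atrophy programme in 18 of 20 (0.00312), both with adjusted p = 0.985 with an estimated correlation. Lower were 18 of 20 genes of the tricarboxylic acid cycle (0.000225), 23 of 31 of fatty acid uptake and oxidation (0.00286), 20 of 28 of calcium handling (0.00443), 16 of 21 of mitochondrial fission and fusion (0.0184) and 14 of 20 fibroblast markers (0.0206). These 5 lists too had adjusted p = 0.985 with an estimated correlation. Of 32 lists 10 were called, 4 higher and 6 lower, and the count was 6 without KO animal 331 and 6 without the 4 arrays at odds with their label. The same omission gave 9 called clusters. Without Ppp3r1 KO animal 335 or without WT animal 415 1 cluster was called.

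The effects of the lines were compared across genes. Over 15252 clusters, which are not independent replicates, Pearson r was 0.0708 and Spearman rho 0.00622, and 50.3% of clusters had the same sign. Without the 4 arrays at odds with their label, chosen after seeing the data by Ppp3cb itself, r was 0.365. That value rests on 2 against 2 arrays in the Ppp3cb line and was not compared with other splits. With all arrays kept, other pairs of splits reached an r of up to 0.474 in size.

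The difference of the KO effects between lines was tested directly. This test too rests on the contradicted labels of the Ppp3cb line, where an effect of the knockout could cancel between the labelled groups. A called difference may therefore reflect the Ppp3r1 line alone. With limma 0 clusters were called, 810 had an unadjusted p under 0.05, and Myh2 came nearest with a difference of 2.21 (SE 0.35, limma adjusted p = 0.0914): its log2 difference was 0.13 (SE 0.25) between the arrays labelled Ppp3cb KO and WT, or -0.04 without animal 12. The next were Kcnq5 at 1.01 (SE 0.20), the glycerol-3-phosphate acyltransferase Gpam at 0.75 (SE 0.18), Esr1 at 0.69 (SE 0.16) and Gbe1 at -0.67 (SE 0.16). Leaving out Ppp3r1 KO animal 335 or WT animal 415 gave 1 call, and leaving out the 4 arrays at odds with their label gave 7. Of 32 lists 13 were called and 0 with an estimated correlation (smallest adjusted p = 0.544 with an estimated correlation), with 20 called without Ppp3r1 KO animal 416. Within lists, Fmod had 1.72 (SE 0.45), Mt2 -2.75 (SE 0.76) and Hdac9 0.53 (SE 0.15), each called over its list alone. The call of Fmod held with each array left out (highest limma adjusted p = 0.0251), that of Mt2 was lost on leaving out any of 10 arrays (0.113 without Ppp3r1 KO animal 331) and that of Hdac9 on leaving out any of 4 (0.0729 without Ppp3r1 KO animal 414).

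Muscle of WT-labelled mice differed strongly between the lines, a comparison in which line, cohort and any batch cannot be told apart and in which 2 of the 4 arrays labelled Ppp3cb WT go against their label. Of 15252 clusters 5343 were called, 3710 higher and 1633 lower in the Ppp3cb line. Array medians over all probe sets also parted by line, as given above, and this too cannot be told apart from line and cohort. Slow fibre proteins were higher in 16 of 16 genes (median 1.61, camera adjusted p = 5.41e-05; adjusted p = 0.893 with an estimated correlation, fry adjusted p = 0.00523), and 14 rose over the list alone. Myh7 was 11.23 ± 0.99 (SD, n = 4) in the Ppp3cb line and 9.32 ± 1.23 (SD, n = 4) in the Ppp3r1 line (limma adjusted p = 0.0153). Myh2 was 2.05-fold higher in the Ppp3cb line (limma adjusted p = 0.00548). Fatty acid uptake and oxidation was higher in 31 of 31 genes (median 0.49) and oxidative phosphorylation in 73 of 76 (median 0.23), with camera adjusted p of 5.41e-05 and 0.000359 and adjusted p = 0.893 with an estimated correlation. Markers of other cell types differed too. Macrophage markers were higher in 12 of 16 genes (median 0.59, camera adjusted p = 0.0373, adjusted p = 0.893 with an estimated correlation, fry adjusted p = 0.0234), with 11 called higher and 2 lower over the list alone. Lymphocyte and neutrophil markers were lower in 6 of 6 (median -0.27, camera adjusted p = 0.0092, adjusted p = 0.893 with an estimated correlation, fry adjusted p = 0.0573). The count of clusters was 3099 without WT animal 336, 3560 without WT animal 413 and 3324 without the 4 arrays at odds with their label.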

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

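The tests of the Ppp3cb level, of Myh2, of the genes beside Myl1 and of the splits for the 4 cluster counts of KO effects were chosen or had a known outcome after the results were seen. The tests near Ppp3r1 and Ppp3cb and the splits for the gene lists, the correlation and the WT comparison were set beforehand.

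Ppp3cb went against the label on 4 of 8 arrays of its line. A probe set outside the deleted part is argued against, since 4 arrays of the line lay more than 0.5 below the range of the intact line. Array medians cannot decide on a general loss of signal on those arrays. They lay within 0.028 of their line's mean over all tested clusters, but quantile normalization makes array medians alike whatever the signal was. On the low arrays Ppp3ca lay between 11.06 and 11.33, against 11.42 to 11.58 on the other 4 of the line. Ppp3cc lay between 9.32 and 9.87 against 9.80 to 9.94, and Ppp3r1 between 9.43 and 9.64 against 9.68 to 10.08. These values argue against a loss as large as that of Ppp3cb shared by these genes, and a smaller or uneven loss stays open. An exchange of labels between the groups needs partners out of place in both, and 2 arrays labelled WT were low where 2 labelled KO were not, so an exchange may account for the values. The first principal component of this line's arrays, the main axis of their variation, held 31.1% of it with Ppp3cb and Ppp3r1 left out. It lay between 4.59 and 15.4 on the 4 low arrays and between -16.2 and -3.22 on the other 4. So other genes parted with the Ppp3cb level too, which does not tell an exchange of labels from an uneven loss of signal. Single wrong labels or samples stay open too, and no biological explanation was tested.

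Myh2 was lower in the muscle labelled Ppp3r1 KO. Signal from paralogous myosin transcripts is argued against, since Myh1 differed by 0.48 in the opposite direction. Less slow muscle in the KO samples is argued against, since the mean of the slow fibre list differed by 0.18 (SE 0.38), but less red, oxidative muscle stays open, since 71 of 76 oxidative phosphorylation genes (median -0.158) and 24 of 31 of fatty acid uptake and oxidation were lower. The difference was -2.10 within the lower and -2.06 within the higher series of animal numbers, 2 KO and 2 WT arrays each, which argues against a difference between these series, and with the series as a block the limma adjusted p was 0.000153. A lower Myh2 transcript level with loss of Ppp3r1 may also account for the values, as a hypothesis found on these data. An effect of the Cre allele itself and a sequence variant under the probes were not tested.

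Several genes near Myl1, the site of the Cre, had low p-values in the Ppp3r1 line, Lancl1 first. DNA carried along with the Cre allele could give such a pattern. With Myl1 and Lancl1 left out, 17 of 129 clusters within 10 Mb (13.2%) had an unadjusted p under 0.05 against 11.7% elsewhere (two-sided Fisher exact p = 0.582), which leaves it open. Around Ppp3r1 the share was 19.6% (9 of 46) against 11.7% elsewhere (two-sided Fisher exact p = 0.105). Around Ppp3cb in its own line it was 3.49% (3 of 86) against 1.72% elsewhere (two-sided Fisher exact p = 0.186).

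Calls were counted over other splits of the arrays. For the counts of 0 clusters the comparison could not come out otherwise and says nothing about chance: all 35 splits of the Ppp3cb line reached 0, as did all 100 pairs of splits for the mean effect and for the difference (highest others 49 and 150). In the Ppp3cb line the highest other split gave 89 clusters and the next 18. The split with 89 is the one that parts the line's arrays by their Ppp3cb level, animals 18, 5, 23 and 24 against the rest, so it is no random grouping. It points to a structure of the samples that goes with the Ppp3cb level and not with the labels, and since a measured value defines it, no gene is reported from it. In the Ppp3r1 line 7 of 35 splits gave as many as the 1 cluster of the labels, the highest other gave 41 and the next 3. Every other split of this line with a call was 1 exchange of arrays away from the labels. Such splits largely keep the labelled groups together, so they say little about what chance gives. The split with 41 is also 1 exchange away from the number series, and whether it exceeds what the highest of many splits gives was not tested.

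The split of the Ppp3r1 line by number series gave 0 clusters and 5 lists. For gene lists 7 of 35 splits gave as many as 10 in the Ppp3cb line (highest other 14) and 4 of 35 as many as 14 in the Ppp3r1 line (highest other 16). In the Ppp3r1 line the other splits that reached 14 were also 1 exchange of arrays away from the labels. For the mean effect 48 of 100 pairs gave as many as 10 (highest other 17), and for the difference 24 of 100 gave as many as 13 (highest other 18). The correlation was as far from 0 in 68 of 100 pairs (largest other size 0.474). Chance is not excluded for the cluster count of the Ppp3r1 line, the 4 list counts and the correlation. It is excluded for the WT comparison, where 1 of 35 splits gave 5343 and the highest other gave 0.

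An array far from the other 3 of its group was found in 11 of 218 pairs of gene and group, where chance alone gives about 10.9. In the Ppp3cb line Rcan1 was 8.59 in the array labelled WT of animal 24, against 10.17 to 10.48 in the others. Tnnt1 was 9.85 and Mbp 7.87 in the array labelled KO of animal 18. Tfap4 was 7.34 in the array labelled WT of animal 12 and Fam43b 7.17 in the array labelled KO of animal 5. In the Ppp3r1 line Rcan1 was 9.77 in WT animal 413, Omp 6.44 and Fam43b 6.41 in WT animal 334, Mef2c 12.64 in WT animal 415, Ugp2 12.42 in KO animal 414 and Btg2 7.84 in KO animal 335.

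In all 13 lists were called in the test of the difference between the lines with the preset correlation, and 0 with an estimated one (smallest adjusted p = 0.544 with an estimated correlation). Since the labels of the Ppp3cb line are contradicted, these calls do not show that the knockouts differ. Higher in the Ppp3cb line's effect, as labelled, were oxidative phosphorylation (camera adjusted p = 1.69e-08), the tricarboxylic acid cycle (4.50e-05), calcium handling (5.71e-05), fatty acid uptake and oxidation (0.000349), tendon markers (0.000349), fast fibre proteins (0.000356), mitochondrial fission and fusion (0.000954), calcineurin regulators (0.00259), fibroblast markers (0.0309) and glycolysis (0.0475). Lower were the atrophy programme (0.000239), the stress response (0.000239) and macrophage markers (0.000954).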

How the results depend on the processing

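The 4 arrays at odds with their label were left out as an alternative chosen after seeing the data; the others were planned. The second deposited table moved nothing, being identical. No paired analysis was possible because the groups compared share no replicate numbers.

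Cluster counts with each array left out in turn ranged from 0 to 2 for Ppp3cb, 1 to 12 for Ppp3r1, 0 to 1 for the mean effect, 0 to 1 for the difference and 3099 to 5784 for WT against WT. List counts ranged from 3 to 11, 9 to 19, 6 to 12 and 12 to 20 for the first 4 of these, and the correlation from -0.0655 to 0.203. The Ppp3r1 count of clusters was 0 with the line fitted alone, 2 with array weights and 2 at a threshold of 0.10, where the difference gave 1. List counts were 4 for Ppp3cb with the filter at the median and 6 after repeated quantile normalization, and with array weights 6 for Ppp3r1 and 6 for the mean effect. With an estimated correlation, and with fry, 0 lists were called in all 4. Without the 4 arrays at odds with their label the cluster counts were 14 for Ppp3cb, 9 for the mean effect, 7 for the difference and 3324 for WT against WT, the list counts 4 for Ppp3cb and 6 for the mean effect, and the correlation 0.365. The cause was not tested, except that leaving out arrays leaves fewer samples.

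Single genes were not run without the 4 arrays at odds with their label, since Ppp3cb itself picked these arrays. Of 2560 values of named genes under the other settings 2532 kept their direction and side of the threshold, 14 became called, 1 lost its call and 13 reversed. This tally is no measure of robustness, since many settings could not move a log2 difference. Among these were the identical second table, changes of the variance prior and omissions in the other line. Almost all named genes were also uncalled in the main fit, so most had no call to lose. Between arrays labelled Ppp3cb KO and WT the log2 difference of Ppp3cb was 0.0161 with array weights and ranged from -0.268 to 0.259 with arrays left out. Ranges that crossed 0 were -0.147 to 0.07 for Ppp3r1, -0.0373 to 0.21 for Myh2, -0.0268 to 0.146 for Ppp3ca and -0.1 to 0.532 for Rcan1. In the Ppp3r1 line they were -0.234 to 0.0843 for Rcan1, -0.0513 to 0.125 for Ppp3cc and -0.0867 to 0.882 for Myh7. The cause was not tested. Myh2 in that line ranged from -2.33 to -1.91 with limma adjusted p from 0.000109 to 0.0202. Over a list alone, Myh1, Gbe1 and Gpam stayed called in the Ppp3r1 line with each of the 16 arrays left out, and every other member called there lost its call without at least 1 array. Values near the filter limit the smaller differences.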

Other observations

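Several single genes passed over lists that were not called as groups in the Ppp3r1 line, each adjusted over the list alone. In glycogen metabolism Gbe1, the branching enzyme, rose by 0.59 (SE 0.11, limma adjusted p = 0.002 over the list alone) and Ugp2, which makes the glucose donor for glycogen, by 0.45 (SE 0.14, limma adjusted p = 0.0471), while 18 of 27 members of the list were lower. The call of Gbe1 held with each array left out (highest limma adjusted p = 0.0119). That of Ugp2 was lost on leaving out any of 12 of the 16 arrays, and without KO animal 414, far from the others of its group, Ugp2 had 0.28 (limma adjusted p = 0.145). In lipid synthesis Gpam fell by 0.56 (SE 0.13, limma adjusted p = 0.00593) and Lpin1, a phosphatidate phosphatase, rose by 0.51 (SE 0.15, limma adjusted p = 0.0433). The call of Gpam held with each array left out (highest limma adjusted p = 0.0232), and that of Lpin1 was lost on leaving out any of 13 arrays, with 0.31 (limma adjusted p = 0.143) without KO animal 414. The histone deacetylase Hdac9 fell by 0.42 (SE 0.10, limma adjusted p = 0.0139) in the denervation list, of which 10 of 19 members were higher, a call lost on leaving out any of 3 arrays (highest limma adjusted p = 0.0719, without KO animal 414). The interferon-induced chemokine Cxcl10 rose by 0.50 (SE 0.14, limma adjusted p = 0.0442), with 8 of 16 of its list higher, a call lost on leaving out any of 12 arrays (highest limma adjusted p = 0.219, without KO animal 414).

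Osteocrin (Ostn), a peptide secreted by muscle, fell by 2.06 (SE 0.54, limma adjusted p = 0.0156 over its list alone, limma adjusted p = 0.363 over all clusters). Its spread was unequal, at 8.62 ± 1.72 (SD, n = 4) in KO and 10.68 ± 0.16 (SD, n = 4) in WT muscle, and without KO animal 416 its log2 change was -2.77 (limma adjusted p = 0.00844 over all clusters). Over its list alone the call was lost on leaving out any of 3 arrays (highest limma adjusted p = 0.0786, without KO animal 331).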
